A study of Mus musculus with 8 samples.

How the data were processed

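Colonic mucosa of C57BL/6 mice was compared at postnatal day 90 between offspring of mothers given a methyl donor diet (MD) and offspring of control mothers. The series held 8 arrays of 2 colours, 4 for RNA and 4 for genomic DNA. On all 8, per the labels, Cy5 carried the MD sample and Cy3 the control sample, so each array gave 1 direct ratio of MD over control and no array had the dyes the other way. RNA input was 0.4 µg, and 4 µg of digested and amplified DNA was labelled for the methylation arrays. The methylation method is the MSAM assay, in which, as general background, restriction digestion and amplification favour fragments whose cutting sites are methylated; the enzymes are not given in the sources used here, so a higher ratio is read only as a higher signal of amplified DNA. The diet's composition is likewise not given in the sources used here. The samples are described as independent comparisons; nothing in the labels ties animals of the RNA arrays to those of the DNA arrays.

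The deposited scanner files give spot intensity per channel on a linear scale, and the authors' log10 ratio of Cy5 over Cy3 for each spot. Per the file headers, the values came from Agilent Feature Extraction 10.5.1.1 with background subtraction and a linear dye normalization, while the submitters' processing notes name version 8.5.1.1. The deposited value table of the series, also a log10 ratio, equalled the scanner log ratio at all 45018 spots of each RNA array and all 105072 spots of each DNA array, so its direction and scale were known. The files hold no mean signal, so the median spot signal was used where a mean signal had been planned. Of the non-control RNA spots, 60.9% to 67.2% were well above background in the control channel and 72.3% to 73.7% in the MD channel; for DNA the shares were 92.1% to 95.0% and 92.2% to 93.1%. The number of arrays, 4 per assay, limits the precision.

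For expression, intensities were corrected with limma's normexp method at an offset of 50 and normalized within each array by loess, with control spots and spots marked as outliers at weight 0 in the loess fit and left out afterwards. Spots of 1 probe were averaged, and probes well above background in either channel on at least 2 arrays were kept. For methylation, the log2 ratio of the processed signals was centred on the median of each array, with no loess, because most probes carry signal. Spots at 1 genomic location were averaged. On each DNA array 3180 to 3661 of 103507 non-control spots were saturated in the MD channel, against 11 to 46 in the control channel. No methylation fit left these spots out, so ratios of the brightest locations are less certain. A region was 2 or more tested locations, each within 500 bp of the next. Coordinates follow the array design, mm9. The gene table used here is of another assembly, so it served only to update expression gene symbols by transcript accession: 21082 of the 30431 tested probes had a symbol. Methylation locations were therefore not named by gene, and the planned gene lists in methylation and the comparison of methylation with expression gene by gene were not run.

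Each feature's 4 log2 ratios were tested against 0 with limma (version 3.58.1, R 4.3.3, statmod 1.5.0, and version 1.17.8 of data.table), using lmFit, eBayes and Benjamini-Hochberg adjustment, with a threshold of 0.05; tests were two-sided. Every adjusted p for a gene, location or region comes from this test. One probe, the brightest on average, stood for a gene. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 35 lists with at least 5 measured genes out of 37. Camera sets a list against the other genes, while fry tests it against no change. The lists covered cell types of the colon wall, immune responses, mucosal defence, one-carbon and lipid metabolism, methylation enzymes, imprinted genes, junctions, transport, the circadian clock, stress responses, developmental regulators and sex-linked genes. The lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined; the exceptions chosen later are named below and in the closing section.

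The rule named the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with 1 sign on all 4 arrays. From each list past the threshold it named up to 4 genes with the smallest p among those in the direction of the list. It also named a fixed set: Dnmt1, Dnmt3a, Dnmt3b, Ppara, Tlr4, Muc2, Lgr5, Xist and Ddx3y. One further gene of the fixed set is not reported here. Muc2 had no tested probe matched to its symbol and was not analysed here. Genes saturated on all 4 arrays were passed over, a step chosen after the data were seen that removed 1 gene from the 10 largest decreases; a probe saturated in both channels has no measured ratio. Since no region passed, the methylation rule named 10 per direction with the smallest unadjusted p among regions with 1 sign on all 4 arrays.

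The deviations of the MD and control channels of 1 RNA array correlated at 0.567, 0.153, 0.446 and 0.457 on arrays 1 to 4, so the 2 channels of an array were treated as a pair, as the labels describe. All 4 RNA arrays lay on 1 slide, so no slide effect could be estimated for them. DNA arrays 1 and 2 lay on slide 1 and arrays 3 and 4 on slide 2; slide was tried as a random block and each slide was fitted alone.

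On simulated data with the spread of the real arrays, the expression test recovered 60% of 50 genes with a log2 ratio of 0.5 and 86% with a ratio of 1, and 2.84% of its calls were false. The region test recovered 2% at 0.5, 48% at 1 and 84% at 1.5, and the location test 0%, 16% and 60%. The simulated noise was independent between features, with spreads shuffled over them. It held no trend of spread with brightness, no saturation and no dye effect, so these rates need not hold for the real calls. Alternatives covered the background correction, the normalization, the filter on dim probes, the deposited ratios, the pairing, the variance model, the threshold, the region definition and leaving out each array. Added after the data were seen were expression fits without saturated probes, with and without the other variance model. Also added were methylation fits on 1 slide, on autosomes, and with the sign of array 3, or of arrays 3 and 4, turned.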

Results

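The data were 4 expression arrays and 4 DNA methylation arrays of mouse colonic mucosa at postnatal day 90. Each array set offspring of mothers given a methyl donor (MD) diet directly against control offspring, to ask whether the diet of the mother left differences in the mucosa of the grown offspring. Values are log2 ratios of MD over control, with the SE of the limma fit over n = 4 arrays. The diet was given to the mothers, and the sample records used here name no mother or litter. The SE therefore measures only the spread between arrays. Expression ratios correlated across the 30431 tested probes at 0.25 to 0.66 between arrays, with the 3 values of 0.25, 0.26 and 0.30 all involving array 2. Probes are not independent replicates.

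The genes with the largest called changes included Dbp, Slc2a5 and Hoxb6, higher in MD mucosa, and Slc15a2, Atp12a and Slpi, lower. The largest increase was in Dbp, a clock-controlled transcription factor, at 1.64 ± 0.35 (SE, n = 4; adjusted p = 0.0399; higher on 4 of 4 arrays); array 2 gave only 0.15, against 1.91 to 2.27 on the others. Tef, its relative, rose by 1.11, with 0.10 on array 2 and 1.31 to 1.54 on the others. Slc2a5, the fructose transporter, rose by 1.33, Cubn, which takes up vitamin B12 bound to intrinsic factor, by 1.16, and the Hox genes Hoxb6 and Hoxd4 by 1.19 and 1.1. Depp1 (1.26), the membrane-curving protein Amph (1.24), the G-protein regulator Rgs2 (1.13) and the monooxygenase Cyp4b1 (1.11) completed the 10 largest increases, with SEs of 0.10 to 0.35, adjusted p of 0.00276 to 0.0408 and higher ratios on 4 of 4 arrays for each.

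The largest decrease was in Slc15a2, a peptide transporter, at -1.85 ± 0.26 (SE, n = 4; adjusted p = 0.0151; lower on 4 of 4 arrays); the deposited log ratio gave -4.06, and the MD channel was not well above background on 1 array. Atp12a, the colonic proton pump subunit, followed at -1.61 ± 0.23. The cysteine protease inhibitors Cstdc5 (-1.30) and Csta1 (-1.27) and the serine protease inhibitor Slpi (-1.16) fell. So did Adamts15 (-1.12), the muscle-type enolase Eno3 (-1.11), the adhesion molecule Clmp (-1.11), the magnesium channel Trpm6 (-1.10) and Abtb2 (-1.09). Their SEs were 0.08 to 0.26 and their adjusted p 0.00222 to 0.042, and each was lower on 4 of 4 arrays. Under median centring Atp12a was at -1.05, Slc15a2 at -1.75 and the other 8 between -0.80 and -0.50, and Adamts15 lost its call (adjusted p = 0.0601).

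**Figure D1:**
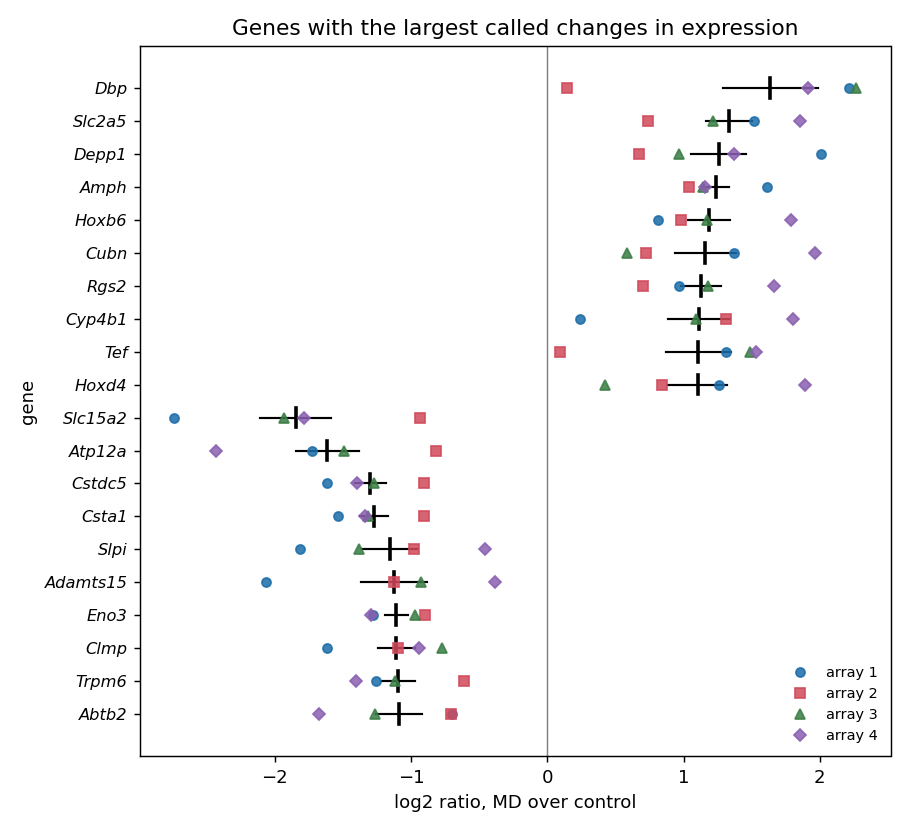
Log2 ratio of MD over control for the 10 genes with the largest called increase and the 10 with the largest called decrease. Each coloured point is 1 of the 4 expression arrays, the vertical bar is the mean and the horizontal line its SE; array 2 lies nearest to 0 for Dbp (0.15) and Tef (0.10).

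Of the 30431 probes, 2763 passed the threshold, 1364 higher and 1399 lower in MD, with a median absolute log2 ratio of 0.36. They stood for 1651 of 14620 genes, 862 higher and 789 lower. Among the lower probes 201 were saturated on at least 1 array, against 8 of the higher; 55 tested probes were saturated in both channels on all arrays and carried no measured ratio, although loess placed them at a median of -1.01. Probes that were never saturated numbered 1356 higher and 1198 lower, with 19 in each direction at 2-fold or more. Every array had MD in Cy5. Other probes of called genes had the sign of the gene's own probe in 612 of 695 cases (88.1%), against 3489 of 5327 (65.5%) for genes that did not pass.

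The number of calls depended on the processing. With limma's trended and robust variance model 221 probes passed, all lower and 130 of them saturated, and without saturated probes 0 passed (smallest adjusted p 0.0782; 8583 probes at an unadjusted p under 0.05 and 4256 at an adjusted p under 0.10), so that each of the 20 genes above lost its call there while keeping its direction. The deposited log ratio gave 1352 calls, of which 746 were shared, and 12 of the 20 genes passed. It placed several named genes further from 0: Nox1 at -1.17, Iigp1 at -1.67, Cry1 at -0.93, Dio3 at -1.28, Mmp7 at 1.16, Plagl1 at 1.15, Fbn1 at 1.099, Reg1 at 0.98, Irak3 at 0.86 and Nod2 at 0.61. Median centring in place of loess moved the median of all tested probes to 0.23. It gave 19423 calls, 79.3% of them higher, against 49.4% after loess. With 15407 of the 30431 tested probes passing as higher there, such a pass of a single gene is no evidence of a rise. Leaving out array 1, 2, 3 or 4 gave 420, 3131, 533 and 358 calls, with 9, 18, 5 and 10 of the 20 genes past the threshold, and treating the channels as unpaired gave 771, with 9 of the 20.

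Gene lists were read against this background. By limma's camera, 9 of 35 lists passed, 2 higher and 7 lower. With an estimated correlation camera passed 0, with 5 lists at an unadjusted p under 0.05, and fry passed 6. Under median centring camera passed 16, but of the 9 only absorptive colonocytes (adjusted p = 0.00305) and mucosal defence (4.85e-05). Others had medians of -0.25 to -0.07: inflammatory cytokines (4e-07), endothelium (6.67e-06), enteric neurons, mast cells and Hox genes (4.85e-05 each) and fibroblasts (5.99e-05). Pancreas (0.000223) and blood (0.00764) lay in that range too. Macrophages (0.000223) and smooth muscle (0.044) had medians of 0.02 and 0.08. Cell cycle (0.00411), PPAR targets (0.0167), unfolded protein response (0.0235) and pattern recognition (0.0243) had medians of 0.45 to 0.57. The median of all tested probes was 0.23 there. Median centring leaves the brightness trend that loess removes, and the 16 passes cannot be told apart from that trend. Of the 142 called list members that were never saturated, 29 turned sign under median centring, 34 came closer to 0 by over 1.5 times and 55 moved further from it, with a median shift of 0.53. Array 2 stood apart in its connective tissue genes: the fibroblast and matrix list had a median of -1.54 there and 0.10 to 0.53 on the other arrays, smooth muscle -0.89 against -0.18 to 0.23, and endothelium -0.91 against -0.03 to 0.29. Other lists short of the threshold passed camera with 1 array left out (smallest adjusted p given). Endothelium was lower without array 1, 3 or 4 (0.00261), smooth muscle lower without array 1 or 3 (0.00571) and immediate early genes lower without array 3 or 4 (0.0323). Without array 3 Paneth genes were higher (0.0177) and MHC class II genes lower (0.0233), and without array 1 blood genes were lower (0.00981), PPAR targets higher (0.0233) and unfolded protein response genes lower (0.0167). Without saturated probes endothelium and inflammatory cytokine genes were lower (0.0495 each).

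Among genes of the mature surface epithelium the calls were mostly lower and often saturated. Of 25 measured genes of absorptive colonocytes, 15 were called lower, but 9 of these were saturated on at least 1 array. The 6 others fell, among them Slc37a2 (-0.91), the chloride and bicarbonate exchanger Slc26a3 (-0.79), the carbonic anhydrase Car4 (-0.79) and the phosphate transporter Slc20a1 (-0.74), which under median centring were at -0.34, -0.19, -0.19 and -0.13. Ceacam20 fell by 0.58 and Slc9a2 by 0.42, but under median centring they were at 0.01 and 0.02. Guca2b rose by 0.50, and 9 genes did not pass. Of the 25, 21 passed when adjusted over the list alone, 5 higher and 16 lower. The list was lower by camera (adjusted p = 7.33e-08; median -0.66, lower on 4 of 4 arrays), with adjusted p = 0.341 with an estimated correlation and 0.0714 without saturated probes, where its median was -0.14.

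Of 17 goblet cell genes, 6 were called lower, 5 of them saturated. St6galnac6, a sialyltransferase, fell by 0.31 and was at 0.29 under median centring, while Galnt12, which starts mucin glycosylation, rose by 0.51, and 10 did not pass. Creb3l1 was at -0.16, the secretory regulator Atoh1 at -0.06 and the antimicrobial Ang4 at -0.39, and under median centring all 3 were above 0; Ang4 was at 1.73 on array 1, and at -1.09 without it, where it passed (adjusted p = 0.0182, lower on 3 of 3 arrays). Under median centring St6galnac6, Creb3l1 and Atoh1 passed as higher (adjusted p = 0.00988, 0.0134 and 0.015), as did 15407 of the 30431 tested probes. In all 8 passed when adjusted over the list alone, 2 higher and 6 lower. The list's call (camera adjusted p = 0.0188; median -0.16, lower on 3 of 4 arrays) ended with an estimated correlation (adjusted p = 0.713 with an estimated correlation), without saturated probes (0.877; median -0.02), under median centring (0.427; median 0.31) and without array 3 (0.0771). Tested against no change by fry, it was at 0.129.

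Enteroendocrine genes rose: 10 of 21 measured passed, 0 fell by limma (0 lower at an unadjusted p under 0.05), and 11 did not pass. The prohormone convertase Pcsk1 rose by 1.0 ± 0.09, secretin (Sct) by 0.79 ± 0.10, chromogranin A (Chga) by 0.44 ± 0.05 and Tph1, which makes serotonin, by 0.41 ± 0.06, each on 4 of 4 arrays. Under median centring these 4 genes were at 1.48, 1.40, 1.04 and 0.96. When adjusted over the list alone, 11 passed. The list was higher by camera (adjusted p = 0.00166; median 0.23, higher on 4 of 4 arrays), with adjusted p = 0.341 with an estimated correlation and 0.408 under median centring.

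T and NK cell genes also rose, in 8 of 24 cases, with 0 falling by limma (0 lower at an unadjusted p under 0.05) and 16 short of the threshold. Lck, the T cell receptor kinase, rose by 0.75 ± 0.06, Cd3d by 0.54 ± 0.05, Cd7 by 0.52 ± 0.06 and the cytotoxic granule gene Nkg7 by 0.48 ± 0.06, each on 4 of 4 arrays. Under median centring these 4 genes were at 1.14, 0.80, 0.90 and 0.78. Adjusted over the list alone 14 passed. The list was higher by camera (adjusted p = 1.15e-05; median 0.19, higher on 4 of 4 arrays), with adjusted p = 0.341 with an estimated correlation and 0.897 under median centring. These are markers of another cell type than the epithelium.

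Interferon response genes were lower as a list, although 40 of 43 measured did not pass singly. The interferon-induced GTPases Iigp1 (-1.02 ± 0.23), Gbp2 (-0.63 ± 0.06) and Gbp3 (-0.59 ± 0.13) fell on 4 of 4 arrays; under median centring they were at -0.83, -0.15 and -0.25, and Gbp2 and Gbp3 lost their calls (adjusted p = 0.116 and 0.115). The RNA sensor Ifih1 was at -0.24 (adjusted p = 0.053, lower on 4 of 4 arrays). Under median centring it was at 0.31 and passed as higher (adjusted p = 0.0059), as did 15407 of the 30431 tested probes. Adjusted over the list alone 14 passed, 2 higher and 12 lower. Camera gave adjusted p = 0.00273 (median -0.13, lower on 3 of 4 arrays), with adjusted p = 0.713 with an estimated correlation, 0.286 by fry and 0.473 under median centring, where the median was 0.31.

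Of 24 antimicrobial and mucosal defence genes, 8 were called lower, 4 of them saturated, 2 rose and 14 did not pass. Besides Slpi, the oxidase maturation factor Duoxa2 fell by 0.95, the acute phase gene Saa3 by 0.69 and the oxidase Nox1 by 0.44; under median centring Duoxa2 was at -0.39 and Saa3 at -0.08. Defb37 (0.91) and Reg1 (0.29) rose. Of the 24, 12 passed adjusted over the list alone, 2 higher and 10 lower. The list was lower (camera adjusted p = 0.000356; median -0.41, lower on 4 of 4 arrays), with adjusted p = 0.378 with an estimated correlation.

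Cholesterol and lipid synthesis genes fell in 5 of 30 cases: Scd2 (-0.60), Msmo1 (-0.47), the sterol regulator Srebf2 (-0.46), Acly (-0.37) and Dhcr7 (-0.33). Under median centring all 5 were above 0. Dhcr7 passed there as higher (adjusted p = 0.0128), as did 15407 of the 30431 tested probes. Insig2 rose by 0.28, and 24 did not pass. The count adjusted over the list alone was 6, 1 higher and 5 lower. Camera gave adjusted p = 0.00166 (median -0.13, lower on 3 of 4 arrays), with adjusted p = 0.713 with an estimated correlation and 0.241 by fry; under median centring the list's median was 0.39 and it did not pass (0.118).

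Of 29 cell junction genes, 10 were called lower, 3 of them saturated, 1 rose and 18 did not pass. Cldn8 fell by 1.03, the tight junction adaptor Cgn by 0.50, Ctnnd1 by 0.42, E-cadherin (Cdh1) by 0.39 and plakoglobin (Jup) by 0.38, while Cldn15 rose by 0.75; under median centring 5 of the 8 calls that were never saturated turned sign, among them Cdh1, Ctnnd1 and Jup, and Cgn was at -0.01. Cdh1 passed as higher under median centring (adjusted p = 0.0211), as did 15407 of the 30431 tested probes. Adjusted over the list alone 16 passed, 2 higher and 14 lower. Camera gave adjusted p = 0.000408 (median -0.20, lower on 4 of 4 arrays), with adjusted p = 0.341 with an estimated correlation; under median centring the list's median was 0.31 (0.528).

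Ion and water transport genes moved both ways. Of 40 measured, 12 were called lower, 2 of them saturated, 3 rose and 25 did not pass. Besides Atp12a and Trpm6, the chloride channel Ano1 (-0.89 ± 0.09), the epithelial sodium channel subunit Scnn1a (-0.69 ± 0.05) and the monocarboxylate transporter Slc16a1 (-0.63 ± 0.05) fell on 4 of 4 arrays; under median centring these 3 were at -0.33, -0.10 and -0.02, and 3 other called genes of the list turned sign. The water channel Aqp1 rose by 0.99, and Fxyd3 and the cotransporter Slc12a2 by 0.45 each. Adjusted over the list alone 23 passed, 7 higher and 16 lower. The call (camera adjusted p = 0.0247; median -0.08, lower on 4 of 4 arrays) ended with an estimated correlation (adjusted p = 0.341 with an estimated correlation), without saturated probes (0.0714) and under median centring (0.106; median 0.10).

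**Figure D2:**
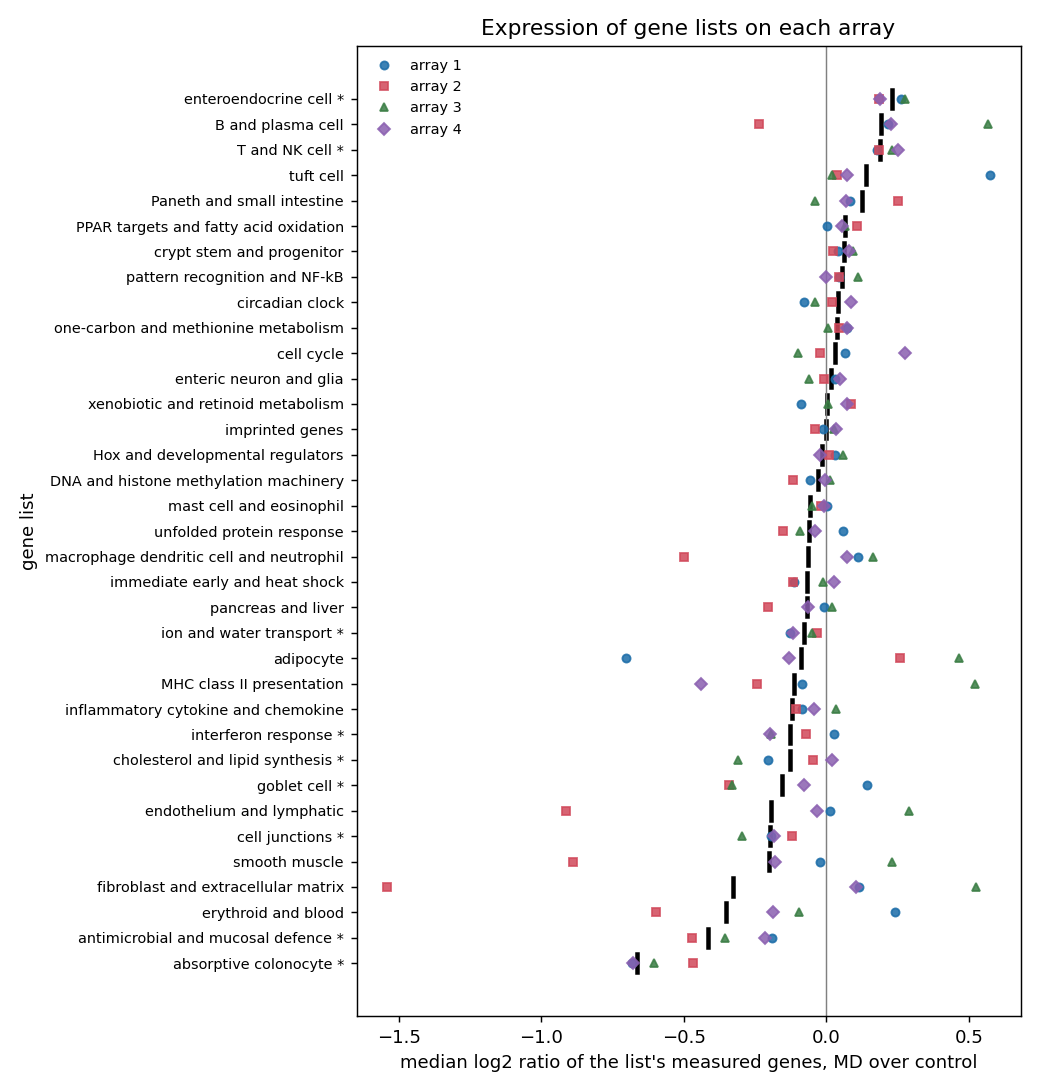
Median log2 ratio of MD over control for the measured genes of each of the 35 tested lists. Coloured points are the 4 expression arrays, and the black bar is the median of the genes' mean ratios. An asterisk marks the 9 lists past the camera threshold, of which 0 passed with an estimated correlation. The median of absorptive colonocyte genes is -0.66 and that of enteroendocrine genes 0.23, and under median centring they are -0.03 and 0.59. Without saturated probes the median of absorptive colonocyte genes is -0.14.

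Other lists did not pass as a whole but held genes that changed. Hox and developmental regulators split, with 8 of 65 rising, 5 falling and 52 short of the threshold (adjusted over the list alone 10 higher and 8 lower; camera adjusted p = 0.885). Hoxb5 (1.04), Hoxb7 (1.01), Hoxb3 (0.64), Hoxb2 (0.49), Hoxb9 (0.40) and Hoxb4 (0.33) rose with Hoxb6 and Hoxd4, while Hoxb13 (-0.78), the endoderm factor Foxa2 (-0.76), Hoxa13 (-0.70), Hoxa10 (-0.63) and Hoxa9 (-0.37) fell; Hoxa9 was at 0.09 under median centring. Circadian clock genes split too, with 3 of 22 rising, 3 falling and 16 short of the threshold (adjusted over the list alone 5 higher and 5 lower; camera adjusted p = 0.838): the repressor Nr1d2 (1.02) rose with Dbp and Tef, while Cry1 (-0.59), Tsc22d3 (-0.50) and Clock (-0.38) fell, the latter 2 being above 0 under median centring.

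**Figure D3:**
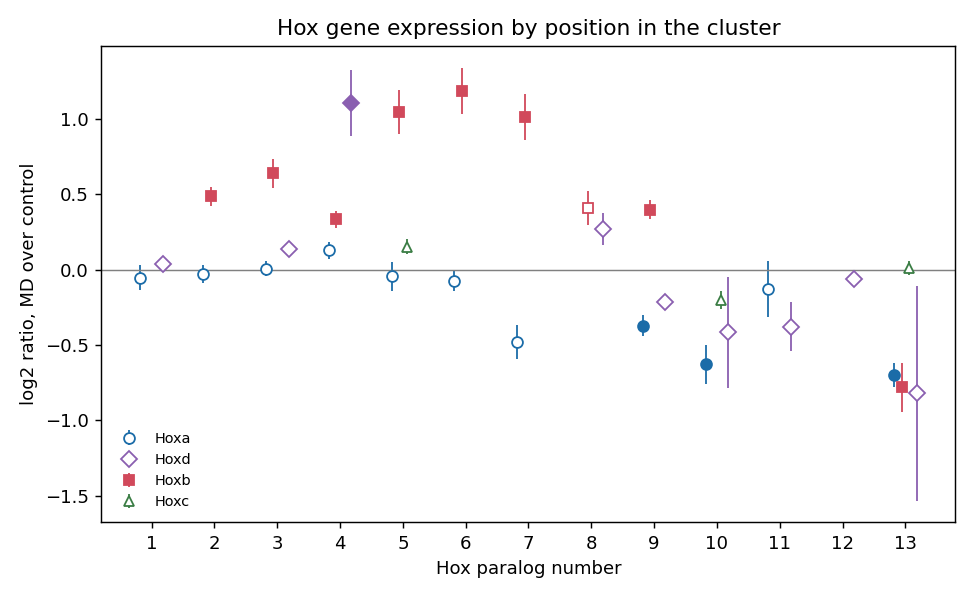
Log2 ratio of MD over control of the 32 measured Hox genes against their paralog number, which follows their order along the chromosome. Points are means over 4 expression arrays with SE bars, colour and shape give the cluster, and filled points passed the threshold; the 8 that rose have paralog numbers up to 9 and the 4 that fell have numbers of 9 or more, of which Hoxa9 is at 0.09 under median centring.

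In one-carbon and methionine metabolism, 8 of 56 genes rose, 3 fell and 45 did not pass (adjusted over the list alone 9 higher and 3 lower; camera adjusted p = 0.463). Cubn rose with its partner Amn (0.79), Psph (0.44) and Mthfs (0.42), while the folate transporter Slc46a1 (-0.88), Ggh (-0.88) and Aldh1l1 (-0.65) fell. Among 36 genes of the DNA and histone methylation machinery, Uhrf2 rose by 0.22, Mbd1 fell by 0.53 (0.04 under median centring) and 34 did not pass (adjusted over the list alone 1 lower; camera adjusted p = 0.28). Dnmt1 was at -0.18 ± 0.08 (adjusted p = 0.214, lower on 3 of 4 arrays) and Dnmt3a at -0.11 ± 0.06 (adjusted p = 0.251, lower on 3 of 4). Dnmt3b was at -0.01 ± 0.06 (adjusted p = 0.889, lower on 2 of 4). Under median centring these 3 were at 0.32, 0.26 and 0.08. Dnmt1 and Dnmt3a passed there as higher (adjusted p = 0.0042 and 0.027), as did 15407 of the 30431 tested probes. Imprinted genes rose in 3 of 41 cases, with Plagl1 at 0.61 and Asb4 at 0.60, and fell in 3, with Dio3 at -0.45, and 35 did not pass (adjusted over the list alone 4 higher and 3 lower; camera adjusted p = 0.645).

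Of 41 PPAR target and fatty acid oxidation genes 7 rose, 1 saturated gene was called lower and 33 did not pass (adjusted over the list alone 9 higher and 2 lower; camera adjusted p = 0.14). Ppara itself rose by 0.75 ± 0.07 (adjusted p = 0.00514, higher on 4 of 4 arrays), as did Vnn1 (0.67) and Eci1 (0.52). Of 47 xenobiotic and retinoid genes 4 rose, among them Ugt2b36 (0.91) and Cyp2d26 (0.89), 6 were called lower, 2 of them saturated, with Rdh16 at -0.53 and Rbp2 at -0.45, and 37 did not pass (adjusted over the list alone 8 higher and 7 lower; camera adjusted p = 0.788). Of 32 immediate early and heat shock genes 6 were called lower, 2 of them saturated, with Fos at -0.78 and Rhob at -0.60, and 26 did not pass (adjusted over the list alone 3 higher and 6 lower; camera adjusted p = 0.066). Unfolded protein response genes gave 2 higher, 1 lower and 24 short of the threshold of 27, with Asns at 0.29 and Calr at -0.38, the latter at 0.18 under median centring (adjusted over the list alone 2 higher and 1 lower; camera adjusted p = 0.0951).

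Among immune lists, 2 of 30 inflammatory cytokine and chemokine genes rose (Ccl5 0.55, Ccl6 0.52), 3 fell (Il18 -0.55, Il1rn -0.47, Ccl28 -0.46) and 25 did not pass (adjusted over the list alone 4 higher and 8 lower; camera adjusted p = 0.0965); Il18 and Il1rn were at 0.02 and 0.04 under median centring. Pattern recognition genes rose in 5 of 33 cases, with Irak3 at 0.48 and Nod2 at 0.38, Tnfaip3 fell by 0.40 (0.13 under median centring) and 27 did not pass (adjusted over the list alone 6 higher and 1 lower; camera adjusted p = 0.217). Tlr4 was at -0.10 ± 0.08 (adjusted p = 0.454, lower on 3 of 4 arrays). Under median centring it was at 0.35 and passed as higher (adjusted p = 0.00659), as did 15407 of the 30431 tested probes. Of 11 MHC class II genes 1 saturated gene was called lower and 10 did not pass (adjusted over the list alone 1 lower; camera adjusted p = 0.622). By limma 0 genes passed among 22 of B and plasma cells, 25 of macrophages, dendritic cells and neutrophils, and 10 of mast cells and eosinophils, with 4, 1 and 3 at an unadjusted p under 0.05, and 0 passed adjusted over the list alone; camera adjusted p were 0.0758, 0.357 and 0.348. Without array 2 the B and plasma cell list was higher (camera adjusted p = 0.000381; median 0.28), and without array 3 the macrophage list was lower (0.0462; median -0.10).

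Crypt stem and progenitor genes rose in 2 of 18 cases, Prom1 (0.56) and Rnf43 (0.25), with 16 short of the threshold (adjusted over the list alone 4 higher; camera adjusted p = 0.449). The stem cell marker Lgr5 was at 0.36 ± 0.10 (adjusted p = 0.0766, higher on 4 of 4 arrays). Over 10 alternatives that kept all arrays it ranged from 0.36 to 0.75 and passed in 1. By limma 0 of 32 cell cycle genes passed, also adjusted over the list alone, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.69). Under median centring the cell cycle list passed (camera adjusted p = 0.00411), with a median of 0.51. Of 13 tuft cell genes 1 rose and 12 did not pass (adjusted over the list alone 1 higher; camera adjusted p = 0.217). Of 16 Paneth and small intestine genes Mmp7 rose by 0.67 and 15 did not pass (adjusted over the list alone 0 by limma, with 5 at an unadjusted p under 0.05; camera adjusted p = 0.13). Among 12 pancreas and liver genes 0 passed by limma, also adjusted over the list alone, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.197).

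Smooth muscle genes gave 2 higher of 19, Acta1 (0.71) and Mylk (0.27), 2 lower, Tpm2 (-0.64) and Smtn (-0.31, and 0.08 under median centring), and 15 short of the threshold (adjusted over the list alone 2 higher and 3 lower; camera adjusted p = 0.066). Of 24 fibroblast and matrix genes Fbn1 rose by 0.48, 1 saturated gene was called lower and 22 did not pass (adjusted over the list alone 1 lower; camera adjusted p = 0.13). Without array 2 the fibroblast list was higher (camera adjusted p = 0.0138; median 0.21), and without array 3 it was lower (0.00835; median -0.55). Of 13 adipocyte genes Lpl (0.70) and Pparg (0.40) rose and 11 did not pass (adjusted over the list alone 2 higher; camera adjusted p = 0.885). By limma 0 genes passed among 18 of endothelium, 17 of enteric neurons and glia and 7 of blood, also adjusted over the list alone, with 2, 4 and 0 at an unadjusted p under 0.05; camera adjusted p were 0.0609, 0.687 and 0.14. The median, mean and camera direction of a list differed in sign for enteric neuron and glia, adipocyte, imprinted, xenobiotic, circadian and Hox genes, none of them past the threshold.

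Among sex-linked genes none passed between the diets, while their signal differed between arrays. Xist, the RNA that coats the inactive X chromosome, was at -0.02 ± 0.15 (adjusted p = 0.936, higher on 3 of 4 arrays; 0.10 under median centring) and the Y-linked Ddx3y at 0.04 ± 0.05 (adjusted p = 0.659, higher on 2 of 4), and 0 of the 4 measured Y-linked genes passed by limma, with 1 at an unadjusted p under 0.05. Xist was well above background in both channels of arrays 1 and 3, at log2 signals of 9.02 to 9.37, where Ddx3y was not. On arrays 2 and 4 Ddx3y was well above background in both channels, at 9.21 to 9.36, and Xist lay at 5.92 to 6.54. Eif2s3y, Kdm5d and Uty were also well above background in both channels of arrays 2 and 4 and in neither of arrays 1 and 3. By these genes both channels of arrays 1 and 3 read as female and both of arrays 2 and 4 as male.

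The methylation arrays asked whether the same diet changed DNA methylation in the mucosa. By limma 0 of 91744 locations and 0 of 19384 regions passed the threshold, with 4572 locations (4.98%) and 545 regions (2.81%) at an unadjusted p under 0.05 and smallest adjusted p of 0.919 and 0.9999. Spots that measured 1 location on the same array correlated at 0.945 to 0.989, so the ratios of 1 array were repeatable. The arrays did not move together: over locations the correlation was 0.46 between arrays 1 and 2 and 0.19 between 3 and 4, the pairs that shared a slide, and -0.48 between arrays 1 and 3. The other pairs lay between -0.11 and 0.02. On autosomes alone the values were 0.33 between arrays 1 and 2, 0.19 between 3 and 4 and -0.55 between 1 and 3. Over autosomal regions the pairs that shared a slide were at 0.24 (arrays 1 and 2) and 0.30 (arrays 3 and 4). The dyes are stated and the pairs are of separate animals, so the direction was kept.

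Of the 545 regions, 365 were lower in MD and 216 of these lay on chromosome X, which held 1.61% of the tested regions; 180 were higher, 0 of them on X by limma at an unadjusted p under 0.05. The lower X ratios lay mainly on arrays 1 and 2 (medians of -0.96 and -0.98, against -0.09 and -0.07 on arrays 3 and 4). Animals of different sex on 1 array are weighed as their cause in the closing section. Of the 10 regions named on the lower side 8 were on chromosome X. One, on chromosome X from 97016551 to 97017100 (mm9, 5 locations), was at -1.39 ± 0.27 (SE, n = 4) and on arrays 1 to 4 at -2.26, -1.92, -0.41 and -0.98. On autosomes the named lower region of smallest p, on chromosome 6 from 53360791 to 53361356, was at -0.78 ± 0.15. It had a low mean log2 signal of 4.44 and values of -0.81 to -0.26 over the alternatives. The named higher region of smallest p, on chromosome 5 from 139494778 to 139495364, was at 0.48 ± 0.12. Only regions with 1 sign on 4 of 4 arrays could be named, so their shared sign is no support. Of all tested regions 9.44% had 1 sign on all arrays, against 12.5% expected with random signs. None of the named regions passed (adjusted p = 1).

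Chromosome X differed between arrays. Its median log2 ratio was -0.96 on array 1, -0.98 on array 2, -0.09 on array 3 and -0.07 on array 4, while the medians of single autosomes lay between -0.06 and 0.06. Set against the autosomes of the same channel, X signal lay at 0.27, 0.29 and 0.28 in the control channels of arrays 1 to 3 and at 0.13 in the MD channel of array 3. It lay at -1.07 in the MD channels of arrays 1 and 2 and at -1.30 and -1.31 in the control and MD channels of array 4.

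**Figure D4:**
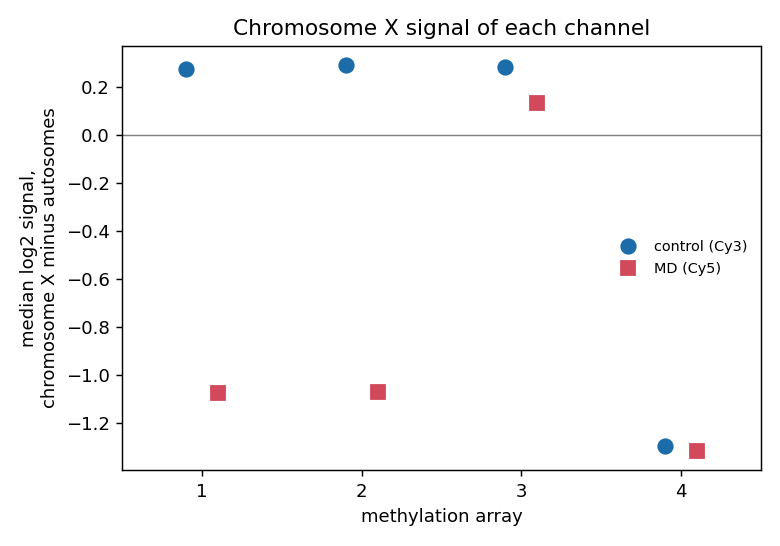
Median log2 signal of chromosome X minus that of the autosomes for each channel of the 4 methylation arrays. Circles are control and squares MD; 4 channels lie between 0.13 and 0.29 and 4 between -1.31 and -1.07, and arrays 1 and 2 hold 1 of each.

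The methylation counts differed between subsets of the arrays. Without array 3, 268 locations and 234 regions passed, 165 of the regions on chromosome X; within slide 1 the numbers were 4943 and 784 (3636 and 461 on autosomes), and within slide 2 they were 0 and 169, each from 2 arrays. With slide as a random block 0 locations and 0 regions passed, with 3192 and 369 at an unadjusted p under 0.05.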

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

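The tests of this part were chosen before their results were seen, with some exceptions. Added afterwards were the fits within 1 slide, on autosomes, and with the sign of array 3 turned, alone or with the other array of its slide.

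Among 139 groups of 4 array values, 6 held an array far from the other 3, measured as its gap to the nearest value over the whole range; chance gives about 1 in 20 groups, or 6.95. For Dbp the share was 0.8335 (array 2 at 0.15, others 1.91 to 2.27) and for Tef 0.8426 (array 2 at 0.10, others 1.31 to 1.54). Ang4 had 0.9542 (array 1 at 1.73, others -1.16 to -1.03) and Ifih1 0.9045 (array 1 at -0.09, others -0.30 to -0.28). The median of the tuft cell list had 0.9044 (array 1 at 0.58, others 0.02 to 0.07) and that of the macrophage, dendritic cell and neutrophil list 0.8635 (array 2 at -0.50, others 0.07 to 0.16).

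Every array had MD in Cy5, so a dye effect could produce expression calls. A bias of single probes is argued against, since other unsaturated probes of called genes had the sign of the called probe in 88.06% of cases. A dye effect shared by whole transcripts cannot be told apart from the diet, because 0 arrays had the dyes the other way. The diet stays open as a biological explanation. So do different positions along the colon for the Hox genes and different times of day for the clock genes, tested under the other observations.

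The lower chromosome X signal in MD on methylation arrays 1 and 2 may come from animals of different sex on 1 array. The 8 channels fell into 2 levels of chromosome X signal with a gap of 1.198 (log2), against a largest range within a level of 0.247, and arrays 1 and 2 each held 1 channel of both. The levels did not follow the diet, since the control channel of array 4 lay at -1.30 and the MD channel of array 3 at 0.13. The labels give no sex. On each RNA array the 2 channels matched in Xist and the Y-linked genes, but nothing ties those animals to the DNA arrays.

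Methylation ratios of arrays 1 and 3, on different slides, ran opposite; no biological explanation was tested. Probe length (as a measure of GC content) with brightness is argued against as the whole cause, since r stayed at -0.426 after both trends were removed from -0.477. Chromosome X is also argued against, with r = -0.553 over autosomes. The other pairs across slides lay between -0.11 and 0.02 over locations and between -0.16 and -0.08 over autosomal regions. A difference between slides stays open, although only arrays 1 and 3 ran clearly opposite. Within slide 1 alone 784 regions passed, 242 of them on chromosome X, and within slide 2 alone 169, 4 of them on X (461 and 152 with autosomes only). With the signs of arrays 3 and 4 turned, 0 locations and 0 regions passed by limma (13231 and 3429 at an unadjusted p under 0.05). Both slide 1 arrays paired channels of different chromosome X level, and both slide 2 arrays channels of 1 level. A slide difference therefore cannot be told apart from that mismatch, and the 2 counts, each from 2 arrays, do not decide it. A swapped label on array 3 stays open too, although with its sign turned only 156 locations and 0 regions passed by limma (1590 regions at an unadjusted p under 0.05).

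The 4 arrays allow 8 settings of their signs, too few for a share under 0.05. For expression 1 of 8 gave as many calls as the real one (2763, highest other 0). For methylation locations (0, highest other 156) and regions (0, highest other 0) 8 of 8 did. With 0 real calls every setting gives as many, so the methylation counts cannot test this.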

How the results depend on the processing

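Alternatives on saturated probes (alone or with the other variance model), single slides, autosomes and turned signs were chosen after seeing the data; the others were fixed earlier. Where no cause is named, the cause was not tested.

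Expression calls (2763) moved to 1352 with the deposited log ratio and the series table, 19423 under median centring, 771 without the replicate block (channels unpaired), 221 with a trended and robust variance model, 0 when that model left out saturated probes (limma; 8583 at an unadjusted p under 0.05), 5505 at an adjusted p under 0.10 and 523 at an unadjusted p under 0.05 with 1.5-fold. Leaving out 1 array gave 358 to 3131 from the arrays that remained, the highest count being that without array 2. They stayed within 1.5 times without background correction (2813), without the filter (3011), with the strict filter (2867) and without saturated probes (2338). The gene lists past the threshold (9) became 16 under median centring, 0 with an estimated correlation (5 at an unadjusted p under 0.05), 6 by fry and 11 to 15 without 1 array. Of the 9, only absorptive colonocytes and mucosal defence were among the 16. Mean agreement between expression arrays was 0.4141, and 0.7194 under median centring.

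Median centring leaves the brightness trend that loess removes, and these turned to: Ceacam20 0.01013, St6galnac6 0.2918, Creb3l1 0.3082, Ang4 0.1911, Atoh1 0.3881, Ifih1 0.3148, Msmo1 0.1314, Srebf2 0.06133, Dhcr7 0.2587, Scd2 0.005483, Jup 0.1344, Ctnnd1 0.06118, Cdh1 0.2326, Dnmt1 0.3201, Dnmt3a 0.2578, Dnmt3b 0.07734, Tlr4 0.3496 and Xist 0.09954. So did the lists of cholesterol synthesis (adjusted p 0.118), cell junctions (0.528) and unfolded protein response (0.0235). Of the turned genes, St6galnac6, Creb3l1, Atoh1, Ifih1, Dhcr7, Cdh1, Dnmt1, Dnmt3a and Tlr4 passed as higher under median centring (adjusted p 0.0042 to 0.027). The others did not pass. Under that scaling 15407 of the 30431 tested probes passed as higher, so these passes alone are no evidence of a rise. Dnmt3b was at 0.02666 with the deposited ratio and the series table.

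Without 1 array, Atoh1 ranged from -0.1243 to 0.0003531, Dnmt3b from -0.04555 to 0.02339, Xist from -0.1459 to 0.1761, and the adjusted p of the fibroblast list from 0.00835 to 0.0575; its median of -0.33 turned to 0.21 without array 2 (adjusted p 0.0138).

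Methylation calls (0 locations, 0 regions by limma; 4572 and 545 at an unadjusted p under 0.05) became 797 and 149 at an unadjusted p under 0.05 with 1.5-fold, 4943 and 784 within slide 1 (3636 and 461 on autosomes), 169 regions within slide 2 (152 on autosomes) and 156 locations with array 3 turned; without 1 array they ranged from 0 to 268 and from 0 to 234. They stayed at 0 unpaired, and with slide as a block. Mean agreement between methylation arrays, 0.01795, was -0.0244 on autosomes and ranged from -0.08771 (without array 2) to 0.1661 (without array 3).

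Over the alternatives other than leaving out an array, single genes kept direction and side of the threshold in 411 comparisons, lost the threshold in 183, gained it in 3 and turned in 20; regions kept them in 243 and gained it in 18. Gene lists in methylation, methylation against expression by gene, and slide as a block for expression (1 slide) were not run. Median signal over background of 2.08 to 2.71 on the expression arrays limits ratios of dim genes.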

Other observations

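Both tests here were written down before they were run, but after some members (Hoxb5, Hoxb6, Hoxb7, Hoxd4, Dbp, Tef, Nr1d2) had been seen, so each is a hypothesis tested on the data that raised it. The tests without those members and within Hox clusters were chosen after the result was seen.

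A candidate explanation for the split of the Hox genes is that MD and control mucosa came from different positions along the colon. Over 32 measured Hox genes the ratio fell with the paralog number (Spearman rho -0.5872, permutation p = 0.00056; Pearson r -0.52, permutation p = 0.0021). Without the 4 Hox genes seen earlier, rho over 28 genes was -0.63 (permutation p = 0.00047), and with paralog numbers permuted within clusters p was 3e-05 (permutation). Within clusters a to d rho was -0.81, -0.37, -0.50 and -0.73. The 13 genes with numbers above 8 had a median of -0.37 and the 19 others 0.15. By array, rho was -0.46, -0.23, -0.60 and -0.53; under median centring it was -0.47 and with the deposited ratio -0.54. Neighbouring Hox genes are not independent, and the labels give no position, so an effect of the diet on these genes stays open.

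A candidate explanation for the clock genes is tissue taken at different times of day. The arm with Arntl, Npas2, Clock, Nfil3 and Cry1 had a median of -0.38, lower in 5 of 5 genes, and the arm with Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per1, Per2, Per3, Ciart, Bhlhe41 and Usp2 one of 0.25, higher in 10 of 11. The medians differed by 0.6329 (permutation p = 0.084, over the threshold), by 0.83 under median centring and by 1.08 with the deposited ratio. On array 2 they were -0.08 and 0.10. Without the 3 clock genes seen earlier the second arm, 8 genes, had a median of 0.16 and the difference was 0.54 (exact permutation p = 0.0155). Time of sampling is not given in the sources used here, and an effect of the diet on the clock stays open.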
